A study of Homo sapiens with 6 samples.

How the data were processed

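RNA-seq values were analysed for 6 libraries of C4-2B cells in 3 experiments, each a vehicle and a treated library with 1 library per group. Libraries were poly(A)-selected and made with a TruSeq kit from total RNA, per the labels' protocols, and the ENZ experiment was sequenced with paired-end reads, per the labels. The files of the SR2211 experiment hold RPKM, read numbers scaled for gene length and mapped reads, computed by the authors and deposited with an Entrez identifier. The files of the XY011 experiment hold FPKM, fragments scaled in the same way, computed by the authors and rounded to 2 decimals. The files of the ENZ experiment hold deposited FPKM values with gene names alone. The submitters' processing notes name BWA, Bowtie, Cufflinks and Cuffdiff and the builds GRCh37 and hg19. Which tool made which table, the versions, the annotation and whether reads were counted by strand are not given in the sources used here, so a gene and its antisense partner cannot be told apart. Genes without reads stood at 0.01 in the SR2211 experiment, at 0.001 in the XY011 experiment and at 0 in the ENZ experiment, and no gene was at that stand-in in both libraries of an experiment. The ENZ table listed genes seen in its vehicle library, where no gene was at 0, while 742 were at 0 with ENZ. Thus an increase from no reads could not appear in that experiment.

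Titles name SR2211 and XY011 for the treated libraries of the first 2 experiments, while the extraction protocol given for both names SR2211 and a different code in place of XY011, and the extraction protocol of the ENZ pair names SR2211. Groups were taken from titles and agents. Spreadsheet software had turned 26, 23 and 22 gene symbols of the 3 tables into dates, and those genes were matched by identifier where one was given. Tables were joined by Entrez identifier for the SR2211 and XY011 experiments (15713 shared genes) and by current or older symbol for ENZ (14093 names matched, 27 by an older name and 8502 unmatched), which left 13478 genes listed in all 3. Symbols on several lines of the ENZ table were summed (94 lines).

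Depth was worked out from the values. In the SR2211 experiment the values of microRNA genes, whose lengths are known, were whole reads at 8.20 M mapped reads for the vehicle library (26 genes, 100% whole within 0.01 read) and at 8.16 M for SR2211 (35 genes, 97.1% whole). Low-level genes gave the same relative depth, 0.996, in 367 of 1593. With this depth, whole read numbers were found for 12837 of 15664 genes at an annotated transcript length (GENCODE 29), 82.0%, and in simulated data the reads of 82.5% of 998 genes were found exactly. The smallest whole numbers that matched were taken, so the true ones can be a multiple of them. Exact 95% intervals of a ratio of reads rest on those smallest numbers and cover counting error only. Where the true numbers are larger, the ratio holds and the interval is too wide. The relative depth of the XY011 pair was 0.864, from 8 of 50 genes, and the ENZ depth was unknown, so no counting interval is given there.

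Changes are log2((treated + 1)/(vehicle + 1)) within an experiment. Genes with a value of 1 or more in either library were tested, small RNA genes were left out, and a gene was called higher or lower at a log2 change of 1 or more. This rule has no p-value. A simulation from the SR2211 pair (12155 genes) used a small spread set by hand and none between separate cultures, so it checked the code alone and gives no rate of false calls. Between the SR2211 and XY011 vehicles the same rule passed 1059 of 12078 genes. The limma package fitted log2(value + 1) over 6 libraries with experiment, a coefficient shared by SR2211 and XY011 and one for ENZ, without trend or robust options. It used 11977 genes with a mean of 1 or more that all 3 tables list, with Benjamini-Hochberg adjustment at 0.05. This fit had 1 residual degree of freedom, so the p-values measure the spread between the 2 compounds in 2 experiments and treat them as replicates of a class, with a prior of 5.41 degrees of freedom and an SD of 0.209 borrowed across genes. Apart from poly(A) selection and the kit, nothing states that libraries of different experiments were prepared alike, and class effects and compound differences are mixed in that spread. On simulated data for this fit (11977 genes), 100% of 100 genes changed by a log2 value of 2 and 100% of 100 changed by 3 were found, with 16 unchanged genes called. That simulation drew independent noise with the fit's own spread and gave both compounds the same change. It held no difference between compounds or cultures, so it also checked the code alone and gives no rate of found or false calls.

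Before the data were examined, 24 gene lists, 5 sets of cell type markers and the rule for named genes were fixed. The rule names receptors and cofactors, such as RORA, RORB, FOXA1, NCOA1 and NCOA3, and the 8 largest increases and 8 largest decreases of each pair. It adds the 10 largest shared changes per direction of SR2211 and XY011, and up to 4 members of each list with the largest change in a comparison. It leaves out small RNA genes and uncharacterised identifiers. Lists are described by their median change against 10000 random lists matched on expression in 20 bins, and were tested with limma's camera, with a preset correlation of 0.01 and with an estimated correlation, and with fry. With an estimated correlation, camera takes its degrees of freedom from the fit, here 1, and fry rests on the same 1. Few lists could pass at that number, so these forms cannot decide whether a list moved. A list with fewer than 3 measured genes was not described, which left the neuroendocrine list to the ENZ pair. The lists share some members, such as ATF3 (integrated stress response and immediate early genes) and SLC7A11 (integrated stress response and NRF2). Some genes and 2 of the lists are not reported here.

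Alternatives were pseudocounts of 0.1 and 5, no minimum or a minimum of 5, centring on the median gene, quantile scaling of each pair, and small RNA genes kept. Others were a size threshold of 1.5-fold, an intensity trend in limma, an adjusted p of 0.1 and vehicles compared as deposited or with the other pseudocounts. A class fit on 4 libraries without the ENZ experiment, the settings applied to list tests, correlations and single named genes, and the summary count of list medians were added after seeing the data. Leaving out 1 compound leaves no residual degree of freedom, so that alternative has no test. No coordinates are given, since the reference used here for lengths and small RNA genes is GRCh38 and the tables were made on an earlier build. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and with limma 3.58.1 in R 4.3.3.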

Results

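C4-2B cells, an established human prostate cancer line derived from LNCaP that metastasises to bone, were grown in medium made mainly with charcoal-stripped serum to imitate castration. RNA was collected 48 h after adding vehicle or a compound. Expression was measured by RNA-seq in 6 libraries from 3 experiments, each with 1 vehicle and 1 treated library. SR2211, a nuclear receptor inverse agonist, was used at 5 µM. XY011, which is known here only by its code name, was also used at 5 µM. Enzalutamide (ENZ), a drug against prostate cancer, was used at 20 µM. The deposited tables listed 17602 genes for the SR2211 experiment, 16293 for the XY011 experiment and 22738 for the ENZ experiment. Depth in the SR2211 experiment, read back from the values of short genes, was 8.20 M mapped reads for the vehicle library and 8.16 M for the treated library. The XY011 library had an estimated depth of 0.864 relative to its vehicle, a ratio shared by only 8 of 50 short genes, and the depth of the ENZ experiment was unknown. With 1 library per group, differences within an experiment had no replicate check, and genes are called higher or lower there by size alone, at a log2 change of 1 or more in either direction.

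The first comparison asked what SR2211 altered. FOXA1 (gene 3169), a pioneer transcription factor, went from 165 to 92.0 RPKM. The smallest whole read numbers that matched its values were 2297 in vehicle and 1275 with SR2211, a ratio of 0.558. The exact 95% interval from these numbers was 0.520 to 0.597 and covers counting error only. True read numbers can be a multiple of these, which would leave the ratio as it is and narrow the interval. The coactivator genes NCOA1 and NCOA3 went from 17.8 to 12.6 and from 5.40 to 10.3 RPKM. RORA, a nuclear receptor gene, went from 0.577 to 1.35 RPKM (52 and 121 reads by the same rule, ratio 2.34, interval 1.68 to 3.30), and RORB was not listed.

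KLK3, which encodes prostate-specific antigen, went from 1357 to 212 RPKM (log2 -2.68), its neighbour KLK2 from 211 to 28.2, the prostein gene SLC45A3 from 67.6 to 7.86 and C1orf116 from 79.9 to 6.90. The other largest decreases were in TM4SF1 (log2 -3.17), a tetraspanin-like membrane protein gene, APLN (-3.01), which encodes the peptide apelin, PGC (-3.0), which encodes pepsinogen C, and ST6GALNAC1 (-2.88), a sialyltransferase gene. CAMK2N1, which encodes an inhibitor of calmodulin-dependent kinase II, was higher, at 10.9 to 53.5 RPKM, and the decarboxylase gene DDC lower, at 14.5 to 5.28.

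Genes of the integrated stress response, which cells switch on when translation or amino acid supply is disturbed, were higher with SR2211 in 18 of 23 measured members, with a median log2 change of 1.79 and none lower. ATF3 went from 6.76 to 145 RPKM, DDIT3 (CHOP) from 20.2 to 302, CHAC1, a glutathione-degrading enzyme gene, from 4.10 to 66.8 and the mTORC1 inhibitor gene DDIT4 from 51.7 to 579.6. The largest increase was in HMOX1, which encodes haem oxygenase 1, at 10.6 in vehicle and 487 RPKM with SR2211 (log2 5.40). The NRF2 list of oxidative stress genes had 6 of 11 members higher and a median of 1.07, with the cystine transporter gene SLC7A11 (log2 2.41) and the glutathione synthesis gene GCLM (2.00) among them. On the p53 target list 6 of 19 were higher, the median being 0.77, led by the stress cytokine gene GDF15, from 175 to 2315 RPKM, and the cell cycle inhibitor gene CDKN1A, from 26.2 to 214. MAP1B (log2 3.58), the ubiquitin ligase gene RNF144B (3.89) and the long noncoding RNA gene LINC01133 (3.58) completed the largest increases.

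DNA replication genes were lower with SR2211 in 23 of 27 members, with a median of -1.48. The ribonucleotide reductase gene RRM2 went from 88.6 to 18.9 RPKM, the replication factor gene MCM10 from 24.1 to 4.70 and the flap endonuclease gene FEN1 from 66.0 to 14.3. Mitosis genes were lower in 10 of 26 (median -0.93), including the kinesin gene KIF20A (log2 -1.56) and BIRC5 (-1.51), which encodes survivin. MYC and ribosome biogenesis genes were lower in 7 of 18 (median -0.85, LDHA from 705 to 154 RPKM). So were heat shock genes in 5 of 10 (median -1.01, HSPH1 from 179 to 50.03) and luminal epithelium genes in 4 of 11, with 1 higher (median -0.69, SPDEF from 129 to 35.6). Circadian clock genes were higher in 6 of 17 (median 0.64), among them NFIL3 (log2 2.13), NR1D2 (1.97) and NR1D1 (1.81), which encodes REV-ERBα. Fatty acid synthesis genes were higher in 4 of 13 and lower in 1 (median 0.31), with the desaturase gene SCD going from 287 to 1346 RPKM and ACSL1 from 108 to 492.

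Medians of the other lists were set against the 95% range of 10000 random lists matched on expression, which describes these libraries. Nuclear receptors and cofactors lay above it (0.29, range -0.40 to 0.21, 2 higher and 1 lower of 19, HOXB13 from 136 to 47.9 RPKM). Hypoxia genes lay below it (-0.60, range -0.44 to 0.29, 1 higher and 2 lower of 13, VEGFA from 25.9 to 195 RPKM), and immediate early genes above it (0.50, range -0.50 to 0.38, 3 of 9 higher, JUN from 12.6 to 28.6). Medians inside that range were found for cholesterol synthesis (-0.19, 1 higher and 2 lower of 24), endoplasmic reticulum chaperones (-0.41) and apoptosis regulators (0.06). The same held for aryl hydrocarbon receptor and drug metabolism genes (0.33), steroid metabolism (-0.36), basal and mesenchymal markers (-0.38) and housekeeping genes (-0.12). The interferon response had a median of -0.02, but 0.06 after centring on the median gene. Across all genes, 620 were higher and 699 lower of 12155 tested. After centring the pair on its median gene, which lay at a log2 ratio of -0.10, 751 were higher and 560 lower, so the share of increases moved from 47.0% to 57.3%.

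XY011 was compared with its own vehicle to ask the same question. FOXA1 went from 142 to 50.7 FPKM, NCOA1 from 22.1 to 14.6, NCOA3 from 3.72 to 6.93 and RORA from 0.310 to 0.870. C1orf116 went from 74.7 to 0.980 FPKM, SLC45A3 from 57.3 to 2.60, the co-chaperone gene FKBP5 from 187 to 13.5 and PMEPA1, a TGF-β pathway inhibitor gene, from 59.4 to 4.93. CAMK2N1 was higher (log2 2.5) and DDC lower (-1.86).

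Integrated stress response genes were higher with XY011 in 17 of 23 (median 1.83), with DDIT3 going from 22.5 to 619 FPKM, ATF3 from 9.62 to 197 and DDIT4 from 34.1 to 522. GDF15 had the largest increase, from 57.3 to 1969 FPKM (log2 5.08), and p53 targets were higher in 7 of 19 (median 0.88), BBC3, which encodes the apoptosis activator PUMA, with a log2 change of 2.27. Immediate early genes were higher in 7 of 10 (median 1.61), including the phosphatase gene DUSP1 (3.45) and CYR61 (2.48). Clock genes were higher in 8 and lower in 1 of 17 (median 0.65), NR1D1 going from 3.95 to 54.5 FPKM and DBP from 5.89 to 35.1. NRF2 genes were higher in 4 of 12 (median 0.57, HMOX1 from 6.51 to 49.2 FPKM). Other large increases were in LINC01133 (log2 3.95), FAM102A (3.92) and PRSS1 (3.90), a trypsinogen gene with close copies that makes its value uncertain, and STBD1 stood at 14.2 FPKM with its vehicle listed at the stand-in for no reads.

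DNA replication genes were lower with XY011 in 24 of 27 (median -2.10), with FEN1 going from 57.2 to 4.65 FPKM, MCM3 from 68.0 to 7.16 and MCM10 from 23.3 to 2.58. Mitosis genes were lower in 2 of 26 and higher in 0, with a median inside the matched random range (-0.30, range -0.44 to 0.20), and the topoisomerase gene TOP2A went from 46.7 to 90.8 FPKM. MYC and ribosome biogenesis genes were lower in 10 of 18 (median -1.04, ODC1 from 447 to 101 FPKM). Heat shock genes were lower in 5 and higher in 1 of 10 (median -1.18, DNAJA1 log2 -1.84), and luminal genes in 6 of 10 (median -1.11, SPDEF -1.69), while E-cadherin gene CDH1 was the 1 luminal gene that was higher (1.3). The other largest decreases were in TM4SF1 (log2 -4.35), MCCC2 (-4.24), a leucine breakdown enzyme gene, AGR2 (-3.95) and the splicing factor gene HNRNPM (-3.77). GAGE12F and TUBA3D, both of families with near-identical copies, were at 32.02 and 16.0 FPKM in vehicle and at the stand-in for no reads with XY011.

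The nuclear receptor list had 5 higher and 3 lower of 18 (median 0.41, matched random range -0.54 to 0.26, GATA2 from 45.6 to 164 FPKM). The endoplasmic reticulum chaperones had 4 higher and 2 lower of 16 (median -0.51, range -0.50 to 0.34), with DNAJB9 at a log2 change of 1.88 and SDF2L1 at -1.44. The aryl hydrocarbon receptor and drug metabolism list was above its range (0.78, 2 of 5 higher, CYP1A1 log2 2.27). Medians of cholesterol synthesis (-0.27, 1 higher and 7 lower of 24), steroid metabolism (-0.64, STS -1.94), hypoxia (-0.15, VEGFA 2.59) and apoptosis regulators (0.20) were inside theirs. So were those of the interferon response (-0.38), basal and mesenchymal markers (0.12) and housekeeping genes (-0.37, ACTB 1.54), as well as fatty acid synthesis (-0.08, but 0.03 after centring and 0.09 after quantile scaling). In all, 956 genes were higher and 1661 lower of 12622 tested. Quantile scaling of the pair gave 1235 and 1261, moving the share of increases from 36.5% to 49.5%, and the median gene lay at a log2 ratio of -0.12.

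ENZ was compared with its vehicle at a dose that differed from that of the other compounds. RORA was at 2.13 FPKM in vehicle and 2.95 with ENZ. FOXA1 was at 309 and 299, NCOA1 at 11.4 and 10.3, and NCOA3 at 3.30 and 4.18. None of these genes passed the size rule. SLC45A3 went from 94.4 to 7.22 FPKM, the cold-sensing channel gene TRPM8 from 97.1 to 9.69, the transcription factor gene MAF from 22.6 to 2.09 and C1orf116 from 65.1 to 7.89, while KLK3 had a smaller decrease (log2 -0.74). PGC, a gastric and prostatic protease gene, went from 21.3 to 0.796 FPKM, and CAMK2N1 from 19.2 to 122.

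Integrated stress response genes were higher with ENZ in 3 of 23 (median 0.60), DDIT4 going from 310.5 to 737 FPKM and ASNS, the asparagine synthetase gene, from 147 to 316. In all, 22 of the 23 had a positive change, and the median lay above the matched random range (-0.21 to 0.12). DNA replication genes were lower in 2 of 27 (median -0.52, range -0.22 to 0.13), CCNE2 from 11.03 to 3.82 and LIG1 from 27.5 to 10.5. Medians were also below the matched random range for MYC and ribosome biogenesis (-0.44, 2 of 18 lower), heat shock (-0.45, 1 of 11) and luminal genes (-0.40, 4 of 11, SPDEF from 153 to 74.0). Others below it were hypoxia (-0.47, 1 of 13, NDRG1 from 290.2 to 84.5), cholesterol synthesis (-0.35, 2 of 24), mitosis (-0.31, 0 of 26) and endoplasmic reticulum chaperones (-0.32, 0 of 16). The nuclear receptor median was above it (0.27, GATA2 from 120.5 to 229). Medians of p53 targets (0.12), NRF2 genes (0.01), clock genes (0.10), immediate early genes (0.15), fatty acid synthesis (-0.13, ELOVL5 log2 -1.88) and apoptosis regulators (-0.13) were inside it. So were those of aryl hydrocarbon receptor genes (-0.17), steroid metabolism (-0.28), the interferon response (-0.08), neuroendocrine genes (0.11, 3 measured), basal and mesenchymal markers (-0.51) and housekeeping genes (-0.17).

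Among the largest increases with ENZ was that of RYR2, a calcium channel gene, from 1.29 to 39.2 FPKM. LRRC14 went from 15.2 to 269, MYOM2 from 0.866 to 13.5 and the noncoding RNA genes LINC01057 from 0.339 to 12.7 and SNHG14 from 137 to 844. RYR2, MYOM2 and SNHG14 hold annotated small RNA genes within their span. Whether reads from those entered the deposited values was not checked. The ARPC4-TTLL3 readthrough, from 0.384 to 7.98 FPKM, overlaps other genes and is uncertain. The largest decreases, apart from PGC and SLC45A3, were in ZNF350, from 32.5 to 1.73 FPKM, and the pseudogene MSX2P1, from 54.3 to 0.205. MGC4771, SULT6B1 and the pseudogene ASNSP5 stood at 86.3, 16.4 and 10.1 FPKM in vehicle and were listed at 0 with ENZ, while the antisense gene TAB3-AS2 was at 11.3 in vehicle and practically at 0. In vehicle, the other experiments had ZNF350 at 3.72 and 3.73, so the ENZ experiment's vehicle stood apart for it. A total of 710 genes were higher and 902 lower of 19259 tested, on a list that holds genes seen in the vehicle library.

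**Figure D1:**
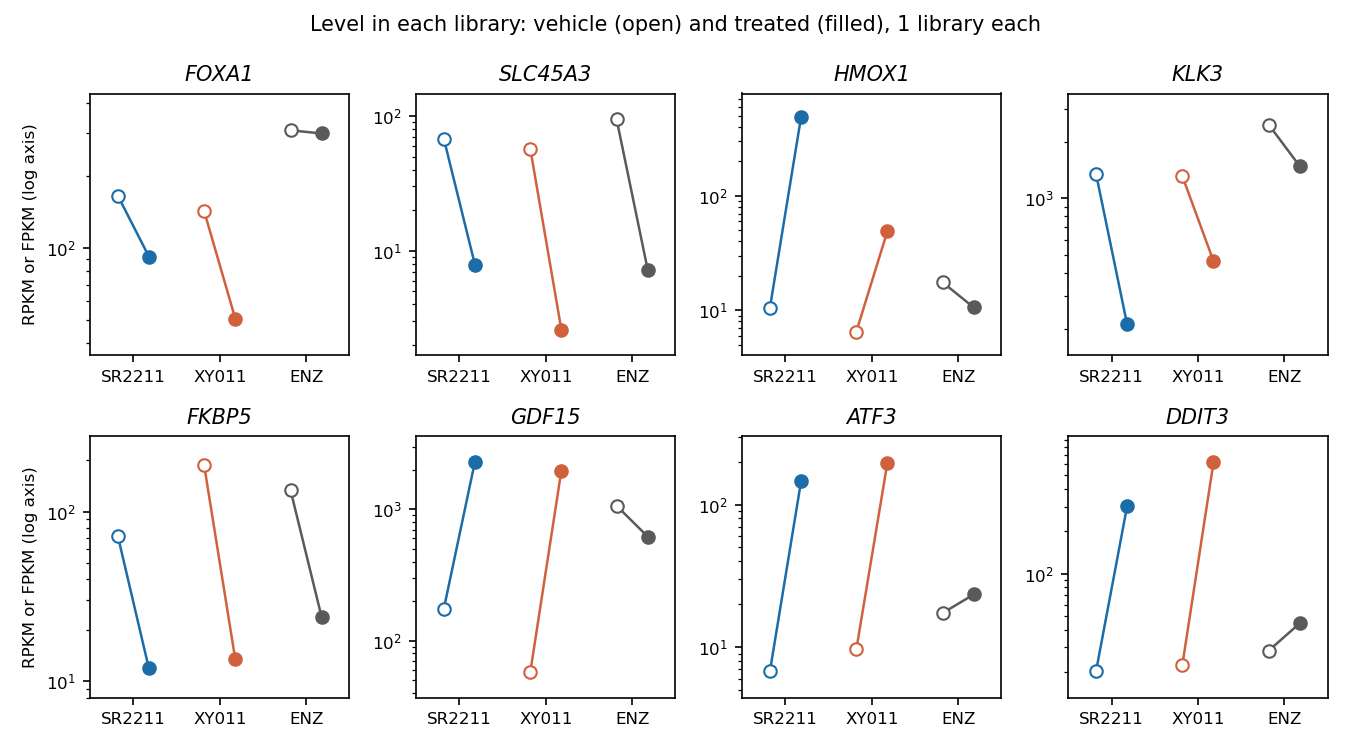
Expression of 8 genes in the 6 libraries, in RPKM for the SR2211 experiment and FPKM for the others on log axes, with open points for vehicle, filled points for the treated library and 1 library per point. ATF3 goes from 6.76 to 145 with SR2211, from 9.62 to 197 with XY011 and from 17.3 to 23.4 with ENZ, whereas FKBP5 is lower in all 3 pairs.

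SR2211 and XY011 were then set side by side at the same dose and time. Among 11637 genes tested in both experiments, 378 were higher with both compounds and 533 lower with both, against 43.1 and 87.6 for independent lists of the same sizes. The 10 genes with the largest shared increases included ATF3 (log2 4.24 with SR2211, 4.22 with XY011), DDIT3 (3.84 and 4.72), and GDF15 (3.71 and 5.08). Others were the calcium-binding protein gene S100P (3.04 and 3.37) and TTC39B (3.07 and 3.37). IFI27L2 stood at 8.10 RPKM and 8.32 FPKM when treated and at the stand-in for no reads in both vehicles. The largest shared decreases included C1orf116 (-3.36 and -5.26), APLN (-3.01 and -3.39), and KLK2 (-2.86 and -2.68). FKBP5 (-2.50 and -3.70) and UHRF1 (-2.51 and -3.37), a maintenance factor of DNA methylation, were also among them. HIST1H2BN, named after its values were seen, was the 1 gene past the size rule in opposite directions, where independent lists would give 125. It stood at 1.09 and 3.55 RPKM in the vehicle and SR2211 libraries and at 4.11 FPKM and the stand-in in those of XY011. Centring each pair on its median gene changed the split to 472 higher and 424 lower, from 41.5% to 52.7% higher.

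The size of the response differed between these compounds for some genes. FOXA1 had log2 changes of -0.84 with SR2211 and -1.47 with XY011. HMOX1 (5.40 and 2.74), GCLM (2.00 and 0.42), SCD (2.23 and 0.77) and KIF20A (-1.56 and -0.32) had larger changes with SR2211. Larger with XY011 were those of NR1D1 (1.81 and 3.49), DUSP1 (1.38 and 3.45) and ACTB (0.20 and 1.54, the former -0.20 after quantile scaling). Over the 911 shared genes, the change was larger with XY011 in 72.0%, with a median absolute log2 change of 1.65 against 1.34. The changes correlated across 11637 genes, which are not independent replicates, with a Pearson correlation of 0.79 and a Spearman correlation of 0.76, and among 8530 genes at 5 or more in both experiments the compounds differed by a log2 value of 1 or more in 392. With 1 pair each, no test of a difference between SR2211 and XY011 could be made. The pairs also differed in unit and in the estimated depth of the treated library relative to its vehicle (0.996 and 0.864).

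**Figure D2:**
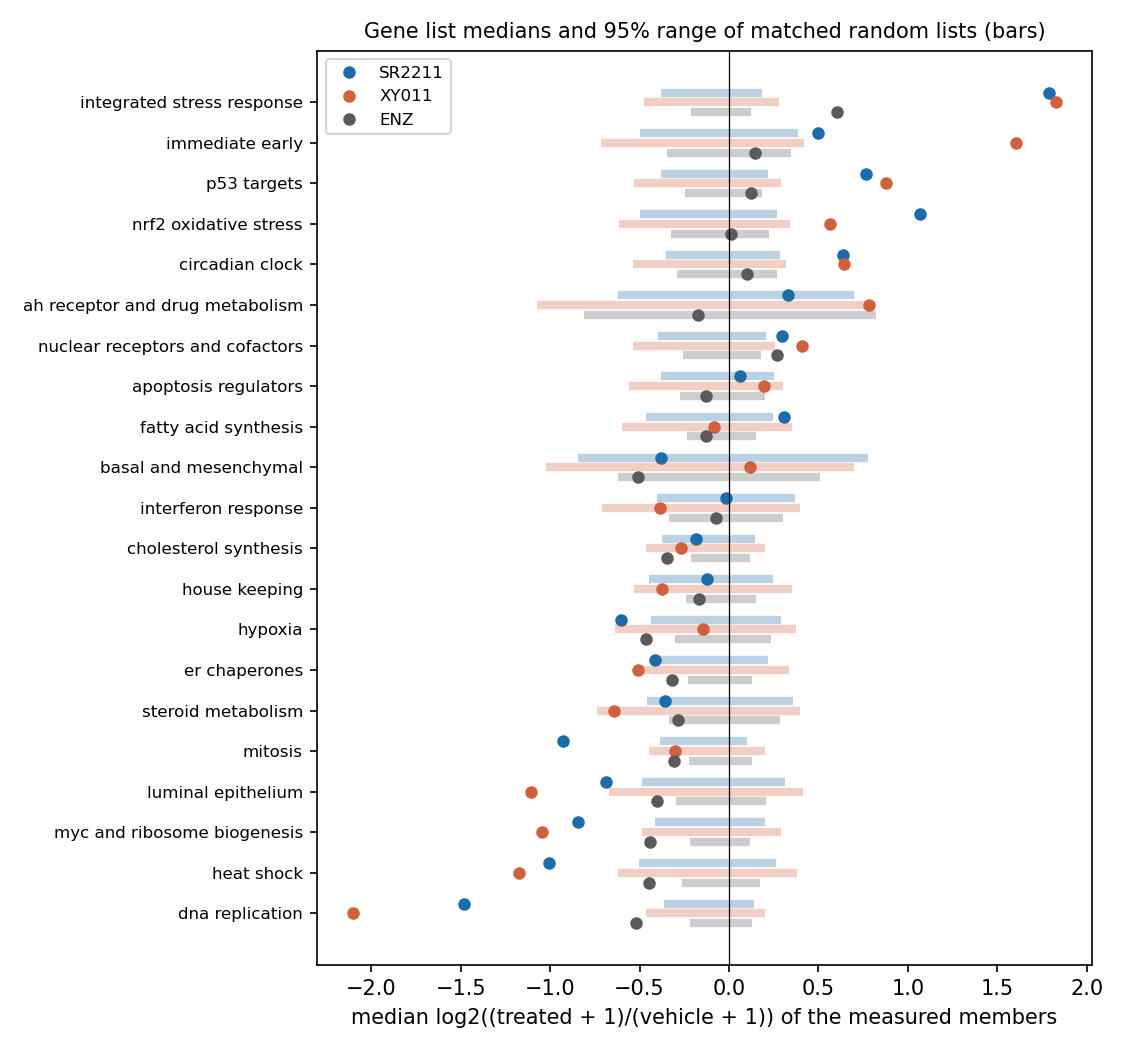
Median log2 change of the gene lists reported here, treated over vehicle with 1 added to each value, in the SR2211, XY011 and ENZ pairs, with bars spanning the 95% range of random lists matched on expression. DNA replication genes lie at -1.48, -2.10 and -0.52, and the integrated stress response at 1.79, 1.83 and 0.60.

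Treating SR2211 and XY011 as a class in limma, with the spread between these 2 compounds as the only error, tested which changes they shared. FOXA1 fell by 1.15 on the log2 scale (SE 0.23, adjusted p = 0.020, lower in both experiments). NCOA3 rose by 0.79 (SE 0.19, adjusted p = 0.0333), while NCOA1 (log2 -0.52, adjusted p = 0.0994) and RORA (0.54, 0.0867) did not pass. HOXB13, a prostate homeobox gene, fell by 1.51 (SE 0.19, adjusted p = 0.00758), and GATA2 rose by 1.43 (SE 0.25, adjusted p = 0.0137). Among 11977 genes, 1124 rose and 1641 fell at an adjusted p under 0.05, and all 883 genes past the size rule in both experiments that could be tested were among them. Both criteria use the same libraries, so this overlap was largely built in and is no separate support. Centring on the median gene gave 1445 rising and 1381 falling, and quantile scaling 1115 and 1078, against 40.7% rising in the main result. With a pseudocount of 0.1 in place of 1 no gene passed in limma (4109 at an unadjusted p under 0.05). The adjusted p of FOXA1 was between 0.00191 and 0.0841 over all settings tried. RORA lay near or under 1 in both pairs, so the size of its change depended on the pseudocount. Its log2 value in the class was between 0.166 and 1.17 over the settings that held it, with a limma adjusted p between 0.0683 and 0.362.

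KLK3 (log2 -2.09) and FKBP5 (-3.10) fell in the class. DNA replication genes fell as a list by limma's camera test with its preset correlation (adjusted p = 5.49e-14) but not with an estimated correlation (0.728), and 24 of 27 fell, 26 adjusted over the list alone, with RRM2 at -2.30. MYC and ribosome biogenesis genes gave 3.05e-06 with the preset correlation and 0.728 with the estimated one, and 11 of 18 fell, 14 adjusted over the list alone (LDHA -2.20). For heat shock genes these values were 0.00627 and 0.728, and 6 of 10 fell, 7 adjusted over the list alone (HSPH1 -2.10). Luminal genes gave 0.0103 and 0.728, and 6 of 11 fell, 7 adjusted over the list alone (SPDEF -1.76), while 1 luminal gene rose, CDH1 (1.18). Mitosis genes gave 0.00102 and 0.789, and 7 of 26 fell, 10 adjusted over the list alone (AURKB -1.19).

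Integrated stress response genes rose as a list with camera's preset correlation (adjusted p = 1.79e-15) but not with an estimated one (0.728), and 19 of 22 rose, 20 adjusted over the list alone, among them ASNS (log2 2.86) and CHAC1 (3.60). For p53 targets the values with the preset and the estimated correlation were 3.99e-07 and 0.728. Of these targets, 11 of 19 rose, 14 adjusted over the list alone (CDKN1A 2.62), 1 member falling by that narrower count. NRF2 genes gave 7.50e-05 and 0.728, and 6 of 11 rose, 8 adjusted over the list alone (TXNRD1 1.2). Clock genes gave 3.54e-04 and 0.728, and 7 of 17 rose, 8 adjusted over the list alone (NR1D2 2.51), while HLF fell (-0.85). Immediate early genes gave 9.31e-04 and 0.743, and 5 of 9 rose, 5 adjusted over the list alone (JUN 1.48). Of 23 lists, 11 passed with camera's preset correlation of 0.01, which is assumed rather than measured here, and none with an estimated one. The estimated form had 1 degree of freedom, so its lack of passing lists cannot decide the matter. For integrated stress response genes the estimated correlation was -0.04, below the preset one, and the list still did not pass. Estimates were -0.09 for NRF2, -0.07 for heat shock, 0.02 for p53, 0.03 for clock and 0.13 for luminal genes. They were far above the preset value for MYC and ribosome biogenesis (0.27), immediate early (0.56), mitosis (0.70) and DNA replication genes (0.72). The preset p-values of these last lists thus assume far less correlation than was estimated, though the estimates rest on 1 residual degree of freedom. The lowest unadjusted p with the estimated correlation was 0.0691. The fry test, which rests on the same 1 degree of freedom, passed no list (lowest adjusted p 0.0806 for one direction and 0.0642 for either).

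Lists that did not pass camera in the class follow, with the adjusted p at the preset correlation in brackets. Nuclear receptors and cofactors had 5 rising and 3 falling of 19, 7 and 4 adjusted over the list alone (0.172). Endoplasmic reticulum chaperones had 4 rising and 4 falling of 16, 4 and 7 adjusted over the list alone (0.627). Cholesterol synthesis had 4 rising and 6 falling of 24, the same counts adjusted over the list alone (0.532), and fatty acid synthesis had 3 rising and 3 falling of 13, 4 and 3 adjusted over the list alone (0.620). Apoptosis regulators had 2 rising and 1 falling of 16, the same counts adjusted over the list alone (0.413), and hypoxia genes had 2 rising and 4 falling of 12, the same counts adjusted over the list alone (0.627). Steroid metabolism had 0 rising and 3 falling of 9, the same counts adjusted over the list alone (0.301). The interferon response had 0 rising and 1 falling of 14, the same counts adjusted over the list alone (0.795), and housekeeping genes had 0 rising and 2 falling of 13, the same counts adjusted over the list alone (0.627). Aryl hydrocarbon receptor and drug metabolism genes had 1 rising and 1 falling of 3, 2 and 1 adjusted over the list alone (0.455), and basal and mesenchymal markers had 1 rising and 1 falling of 3, the same counts adjusted over the list alone (0.806). Members moved apart in several of them. DNAJB9 (1.42) and HERPUD1 (1.12) rose while SDF2L1 (-1.28) and MANF (-0.94) fell. In lipid synthesis TM7SF2 (1.93) and SCD (1.5) rose while ELOVL5 (-1.13) fell. VEGFA, the angiogenic growth factor gene, rose (2.73) while the hypoxia gene ANKRD37 fell (-1.47). CAMK2N1 rose (2.35) and DDC fell (-1.58). Fatty acid synthesis had a median of -0.10 but a mean of 0.19 and an upward test, and the basal list a median of 0.05 and an upward test but a mean of -0.02.

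The class was then tested against ENZ in the same limma fit, which assumed that the single ENZ pair varied as the class pairs did. FOXA1 differed by -1.11 on the log2 scale (adjusted p = 0.277), which did not pass. Of 11977 genes 4 passed, among them ATF3 and ZNF350 on the side of the class and RYR2 on that of ENZ, with 1902 at an unadjusted p under 0.05. With a pseudocount of 0.1, quantile scaling or small RNA genes kept, no gene passed in limma (1348, 1816 and 1860 unadjusted). With camera's preset correlation, integrated stress response genes were higher in the class than with ENZ (median difference 1.47, adjusted p = 2.04e-13). With an estimated correlation, a form with 1 degree of freedom that cannot decide, they did not pass (0.672). In this list 1 of 22 members passed over all genes and 14 over the list alone. The same held for p53 targets (median difference 0.71, adjusted p = 3.31e-06, estimated 0.672), where 0 of 19 members passed over all genes and 5 over the list alone, and for NRF2 genes (median difference 0.67, adjusted p = 0.00116, estimated 0.672), where 0 of 11 members passed over all genes and 4 over the list alone. It also held for clock genes (median difference 0.50, adjusted p = 7.58e-04, estimated 0.672), where 0 of 17 members passed over all genes and 3 over the list alone, and for immediate early genes (median difference 1.05, adjusted p = 6.55e-04, estimated 0.672), where 1 of 9 members passed over all genes and 1 over the list alone. DNA replication genes were lower in the class as a list with the preset correlation (median difference -1.29, adjusted p = 1.58e-11) but not with the estimated one (0.672), and 0 of 27 members passed over all genes and 18 over the list alone. MYC and ribosome biogenesis genes were lower as a list at the preset correlation alone (median difference -0.67, adjusted p = 0.00128, estimated 0.672), although 0 of 18 members passed over all genes and 0 over the list alone. Estimated correlations far above the preset one held here too for DNA replication (0.72), immediate early (0.56) and MYC and ribosome biogenesis genes (0.27). No other list of the 23 passed, but 8 did with a minimum of 5 or quantile scaling and 11 with a pseudocount of 5. Where lists did not pass, an upward test stood beside a mean below 0 for nuclear receptors (mean -0.06), the interferon response and housekeeping genes (mean -0.006). It stood beside a median below 0 for housekeeping genes (-0.11) and chaperones (-0.07).

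Across all 3 experiments, 57 genes were higher and 100 lower with every compound among 11188 tested, against 1.04 and 2.27 for independent lists. They included CAMK2N1, DDIT4 and ASNS among the increases, with ENZ log2 changes of 2.60, 1.24 and 1.1, and PGC, SLC45A3 and AGR2 among the decreases, at -3.63, -3.54 and -2.34. SR2211 and ENZ shared 80 higher and 119 lower genes of 11568 (16.3 and 18.5 for independent lists), with a Pearson correlation of 0.43 across genes, and XY011 and ENZ 99 and 145 of 11542 (23.5 and 42.2), with one of 0.37. The excess of decreases depended on the scaling. SR2211 and ENZ shared 103 higher and 106 lower after centring on the median gene, but 87 and 107 after quantile scaling. XY011 and ENZ shared 113 and 130 after centring, but 125 and 125 after quantile scaling. For all 3 compounds the excess stayed under both (72 and 88, and 64 and 88). Genes past the rule in opposite directions numbered 8 for SR2211 and ENZ and 14 for XY011 and ENZ, against 34.8 and 64.8.

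The vehicles showed how far the experiments differed before any compound. GDF15 stood at 175 RPKM in the vehicle of the SR2211 experiment and at 57.3 and 1064 FPKM in those of XY011 and ENZ, and FOXA1 at 165, 142 and 309. These are deposited values, and all values of the 3 vehicle libraries summed to 402107, 479264 and 1.73e+06. Part of such a contrast can therefore be scale. After quantile scaling over shared genes, 1059 of 12078 genes passed the size rule between the vehicles of SR2211 and XY011, 3102 of 12149 between those of SR2211 and ENZ, and 3736 of 12230 between those of XY011 and ENZ. Of markers of other cell types, COL1A1, a fibroblast collagen gene, stood at 3.70 and 5.62 RPKM in the SR2211 pair, 2.00 and 3.45 FPKM in the XY011 pair and 14.1 and 34.8 FPKM in the ENZ pair. Of 8 fibroblast markers, 5 reached 1 in any library. Leukocyte markers did so in 3 of 9, with CD68 highest at 13.1, osteoblast markers in 1 of 6 (RUNX2, 1.96), basal epithelium markers in 2 of 5 (KRT14, 3.39) and endothelium markers in 0 of 6.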

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

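The tests of the stress response pattern in this part were chosen after the result was seen, and its chaperone test replaced one on the list median alone, which decided nothing. In the limma fit, 4 genes differed between the class of SR2211 and XY011 and ENZ, among them ATF3, RYR2 and ZNF350. ATF3 was 3.82 higher on the log2 scale in the class (adjusted p = 0.0499, past the threshold in 4 of 8 other settings with adjusted p from 0.00254 to 0.439), with changes of 4.24, 4.22 and 0.41 in the SR2211, XY011 and ENZ pairs. RYR2 had a difference of -4.39 (adjusted p = 0.0499, past the threshold in 3 of 8 other settings with adjusted p from 0.00683 to 0.439), with changes of -0.07, -0.46 and 4.13. ZNF350 had a difference of 3.85 (adjusted p = 0.0499, past the threshold in 3 of 8 other settings with adjusted p from 0.00683 to 0.439), and the ENZ experiment's vehicle held 32.5 FPKM against 1.73 to 4.73 in the other 5 libraries.

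Integrated stress response genes, ATF3 among them, had medians of 1.79 with SR2211 and 1.83 with XY011, against 0.60 with ENZ, which also lay above its matched random range. A few genes taking most of the reads would have shifted other genes alike, but the smaller of the 2 medians was 1.89 after each pair was centred on its median gene. A difference in depth is argued against in the SR2211 pair by a depth ratio of 0.996. In the XY011 pair that ratio was 0.864, from 8 of 50 genes, so depth is not argued against there. The values are already scaled for mapped reads, so this ratio alone cannot decide whether depth played a part. An unfolded protein response in the endoplasmic reticulum, which shares DDIT3 and ATF3, cannot be told apart from one without it. Chaperone members moved both ways (DNAJB9 0.95 and 1.88, SDF2L1 -1.12 and -1.44), with a positive change in 7 and 5 of 16 with SR2211 and XY011. Their medians were -0.41 and -0.51, the second just below its matched random range, but the smaller upper 95% bound of the median was 0.63. Whether the response may follow from the compounds' intended target or from another effect at 5 µM was not tested, because each compound was used at 1 dose.

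Of 11188 genes tested in all 3 pairs, 178 were higher with ENZ and with neither of the other compounds, a set without RYR2, which stayed under the minimum in the XY011 pair. MYOM2, under the minimum in the SR2211 and XY011 pairs, and SNHG14, not listed there, were also outside this set. Of the set, 18.5% hold a small RNA gene (upper 95% bound 25.04%) against 18.6% of the others, with a two-sided Fisher's exact p of 1. This argues against reads from such genes as a common cause within the set. It counted any small RNA gene within the gene's span, introns and either strand included, so whether such reads entered the values was not checked. For RYR2 such reads stay open as an explanation, because it does hold a small RNA gene, as do MYOM2 and SNHG14, which also had large increases with ENZ. Noise at a low level could also play a part and stays open, the median of the larger value being 14.5 FPKM in the set and 21.3 in the others. An effect of ENZ itself cannot be told apart from a peculiarity of the 1 ENZ library, for which the design holds no replicate.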

How the results depend on the processing

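The class fit on 4 libraries, the settings of list tests, correlations and single named genes, and the count of list medians were chosen after seeing the data. The cause was not tested for any of these changes, except that other thresholds and minimums admit more or fewer genes by construction. SR2211 genes changed numbered 1319, but 2018 with a pseudocount of 0.1, 557 with 5 and 3769 at 1.5-fold. XY011 genes changed went from 2617 to 1060 with a pseudocount of 5 and 5651 at 1.5-fold. ENZ genes changed went from 1612 to 2769 and 463 with pseudocounts of 0.1 and 5, 990 with a minimum of 5 and 4632 at 1.5-fold. Genes changed by both SR2211 and XY011 went from 911 to 416 with a pseudocount of 5 and 2675 at 1.5-fold, and by all 3 compounds from 157 to 261 and 60 with pseudocounts of 0.1 and 5 and 705 at 1.5-fold. With pseudocounts of 0.1 and 5 and at 1.5-fold, genes changed by SR2211 and ENZ went from 199 to 355, 73 and 935, and by XY011 and ENZ from 244 to 405, 79 and 1003. The limma class test passed 2765 genes, 0 with a pseudocount of 0.1 (4109 unadjusted), 4228 at an adjusted p of 0.1, and 2193 to 3526 in the other settings, with 2689 on 4 libraries. The main fit matches the ENZ pair exactly, so leaving it out keeps the class coefficients and residuals. The 4-library fit is therefore no separate check. The class minus ENZ test in limma passed 4, but 0 with a pseudocount of 0.1, quantile scaling or small RNA genes kept, 1 with a minimum of 5, 7 after median-centring, 70 with a trend and 21 at an adjusted p of 0.1 (1348 to 2167 unadjusted). Camera passed 11 lists in the class and 0 with an estimated correlation, and in the class minus ENZ 7, 11 with a pseudocount of 5, 8 with a minimum of 5 or quantile scaling and 0 with an estimated correlation. The estimated form had 1 degree of freedom in each case, so its counts of 0 decide nothing. Between vehicles, 479, 1672 and 2021 genes passed the rule with a pseudocount of 5, from 1059, 3102 and 3736. Medians outside the matched range numbered 39, and 37 to 40 otherwise. Of 3624 values of named genes, 3467 kept their size within the spread used and 157 moved; of 483 list medians 39 moved. In the class test, 1321 of 1483 calls of named genes stayed on their side of the threshold (158 of them in the 4-library fit), 144 were lost (118 with a pseudocount of 0.1) and 18 gained, and no called value changed direction. Leaving out a compound left no residual degree of freedom. The class test already sets each treated library against the vehicle of its experiment, and within an experiment no paired test exists with 1 library per group. Depth limited genes under about 1 RPKM or FPKM, where the pseudocount sets the change.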

Other observations

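Gene families outside the fixed lists were set against the 95% range of matched random lists, without a test. All 11 families described or counted in this part were chosen after their values were seen. Aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, were higher in 8 of 20 with SR2211 (median log2 change 0.79) and in 6 of 20 with XY011 (0.55), with 2 lower, against 0 of 20 with ENZ (0.11), all 3 medians above that range. SARS went from 55.1 to 213 RPKM with SR2211 and from 102 to 445 FPKM with XY011, and GARS from 105 to 402 and from 111 to 342. Fanconi anaemia and homologous recombination genes, which repair DNA breaks and crosslinks, were lower in 6 of 21 (median -0.78), 10 of 21 (-0.96, with 1 higher) and 3 of 21 (-0.29) with SR2211, XY011 and ENZ. These medians lay below the range. EXO1 went from 17.4 to 5.85 RPKM and from 18.6 to 3.00 FPKM with SR2211 and XY011, and BARD1 from 53.5 to 13.4 FPKM with ENZ.

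Genes of the mitochondrial ribosome had medians of -0.38, -0.57 and -0.18 over 76 genes in the SR2211, XY011 and ENZ pairs, all below the range, with 1, 11 and 0 lower. In contrast, 77 cytosolic ribosomal protein genes had medians of 0.24, 0.38 and 0.03, above the range with SR2211 and XY011 and inside it with ENZ, with none past the size rule. After quantile scaling the cytosolic medians were 0.084 and 0.189 with SR2211 and XY011, under the upper bounds of 0.110 and 0.194 from the unscaled changes. No range was made after scaling, so their place above the range rests on the unscaled values. Neither family's median changed sign under any scaling. Lysosomal genes, counted together with the autophagy genes SQSTM1 and GABARAPL1, had medians of 0.26, 0.39 and 0.18, all above the range, with 5, 3 and 0 of 23 higher and 1 lower with XY011. GABARAPL1 had the largest change of this family with both compounds, from 9.51 to 42.6 RPKM with SR2211 and from 9.98 to 59.0 FPKM with XY011, while MCOLN1 went from 8.76 to 2.35 FPKM with XY011. Proteasome subunit genes had medians of -0.33, -0.51 and -0.23, with 0, 4 and 0 lower, inside the range with SR2211 and below it with XY011 and ENZ. Nuclear pore genes (-0.33, -0.50 and -0.17) were inside it except with XY011, at its lower edge. Medians inside the range in every pair were those of complex I (-0.15, -0.30 and -0.06, the last 0.01 after quantile scaling) and V-ATPase (-0.03, -0.30 and -0.22, the first 0.06 after either scaling) genes. So were those of amino acid transporter (0.35, 0.33 and 0.08) and interleukin and chemokine genes (-0.30, -0.59 and 0.40).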
